A study of Mus musculus with 12 samples.

How the data were processed

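Read counts per gene were taken from synovial membrane and fat pad tissue of SKG/Jcl mice. The 12 libraries formed 3 groups of 4. They are called here Sedentary, Mannan-only, after its treatment, and AREx, and the columns headed S in the table were taken as Sedentary. Per the labels' protocols, RNA was extracted with an RNeasy Plus Mini kit, poly(A) RNA was selected, and libraries were made with the NEBNext Ultra II RNA kit. Per the labels, the reads were placed on the genome build GRCm39. The authors' aligner, counting program and use of strand are not given in the sources used here, so genes that overlap on either strand, and near-identical family members, were treated as uncertain.

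The deposited table gave whole read counts per gene, headed total counts per the file headers, for 25655 genes, of which 6984 had no read in any library. The authors also deposited RPKM values, read counts scaled by gene length and library depth, named so per the file headers, which were used here only with the counts to recover the gene length the authors used. The authors' deposited log2 fold changes and adjusted p-values (FDR) for the same 3 comparisons were used only as a second source beside the tests made here. The model behind the authors' comparisons is not given in the sources used here. In the authors' deposited p-value columns a value of exactly 0 also stood in genes with no test, so those genes were left out of counts from that table. Gene positions are those of the deposited table, per the file headers. Total counts per library ran from 11803882 to 17650156. Fold changes, errors and tests printed without a source are from the fits made here.

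Genes were filtered with filterByExpr of edgeR (minimum count 10 in its default form), which left 14278 genes. Counts were scaled by TMM, and all 12 libraries were fitted in 1 model with a mean per group, so that the groups shared an estimate of the spread. Genes were tested with edgeR's quasi-likelihood F test (robust fit), and p-values were adjusted by Benjamini-Hochberg over all genes of a comparison. A gene was taken as changed at an adjusted p under 0.05. The standard error (SE) of a log2 fold change was taken as its size divided by the square root of F. Levels are depth-scaled counts (CPM) on TMM library sizes, and log2 CPM used a prior count of 2. Each of the 3 comparisons is a family of its own.

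Lists of marker and pathway genes were written down before the data were examined, 49 lists with 752 genes, of which 745 were in the table and 711 were tested. A list needed 5 measured members. Lists were tested against all other genes with camera of limma at a preset correlation of 0.01 between genes, adjusted by Benjamini-Hochberg over the 49 lists, and again with the correlation estimated from the data. The test fry, which asks whether a list's own genes move one way on balance, was run beside it. Counts of members are given over all genes tested and adjusted over the list alone. For 6 lists that follow tissue composition, the mean log2 CPM over members was compared between groups by an exact permutation test, two-sided, over 70 label assignments, for which the smallest p is 0.0286. Scores of all 49 lists were tested this way and adjusted by Benjamini-Hochberg over the 49, and the text reports the 6.

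The genes named were set by a rule made before the data were examined. They are up to 10 genes per direction with the largest fold changes among changed genes with a mean of at least 5 CPM in the higher group, a named symbol and groups that did not overlap. Where fewer than 5 genes passed, the 10 smallest p-values were named. Added to these are up to 4 members with the smallest p of each list called, 19 fixed readouts of inflammation, joint damage, fat and cell death, Zap70, and, for AREx against Mannan-only, the largest arthritis genes. The text names part of that set, and some genes are not reported here. Members that moved against their list, and clock genes outside the rule (Nr1d1, Npas2 and others), were named after their values were seen.

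For genes with no read in a group, the fold change is a lower bound computed with 3 counts over the whole group. With 1 to 3 counts, the ratio has a 95% counting interval. Such intervals and bounds cover counting error only.

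The share of arthritis genes with an opposite sign in AREx against Mannan-only was set beside 20 simulations of unchanged groups, 20 with an arthritis effect and no exercise effect, and splits of the Mannan-only libraries into 2 and 2, because both comparisons share the Mannan-only libraries. For the overlap of both comparisons with Sedentary, the Sedentary libraries were split in the same way. The gene and list tests were tested on simulated data, counts drawn for the 14278 genes with 200 genes changed by known amounts.

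Alternatives chosen before the data were examined were DESeq2 size factors, upper-quartile scaling, the DESeq2 Wald test, limma-voom with and without sample quality weights, no filter on low counts, a stricter filter (5 CPM in 4 libraries), fits with only the 8 libraries compared, the replicate number as a block, the skeletal muscle score as a covariate, and leaving out each library in turn. Chosen after seeing the data were fits without AREx replicates 1 and 4, fits without AREx replicates 2 and 4, and removal of each library's trend on gene length (lowess, span 0.3). Immunoglobulin and T cell receptor constant genes (Ighm, Ighd, Igkc, Iglc2, Trac and Trbc2) were listed at 0 reads in every library and could not be used. No reads or alignments were used here.

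Computations were made with R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.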

Results

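Messenger RNA was measured in the lining membrane of the joint together with its fat pad, from SKG/Jcl mice. This strain carries a mutation in the T cell kinase gene Zap70 and is prone to autoimmune arthritis. The Sedentary group received PBS, the Mannan-only group received 20 mg of mannan, a yeast cell wall sugar used to start the arthritis, and the AREx group received the same dose of mannan and ran on a treadmill at low intensity. Each of the 3 groups had 4 libraries. Total counts per library were 13459509 to 17248088 in Sedentary, 11803882 to 12918609 in Mannan-only and 12439229 to 17650156 in AREx. Means are depth-scaled counts (CPM) ± SD over n = 4 libraries, and fold changes are on the log2 scale with a standard error (SE). The labels do not say whether each library came from a separate animal, so every p-value measures the spread between these libraries. Mitochondrial genes took 5.9% to 7.57% of the counts in Sedentary and 2.87% to 3.95% in Mannan-only and AREx.

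The main axis of variation, with 68.9% of the variance over genes, set every Sedentary library apart from every mannan library. The next axis held 14.7% and set AREx replicate 1 (score 89.5) and AREx replicate 4 (47.6) apart from AREx replicate 2 (-13.5) and AREx replicate 3 (-19.4). Those libraries also held more counts in short genes. The median log2 ratio to the Mannan-only mean in the shortest quintile of genes was 0.86 in AREx replicate 1 and 0.57 in AREx replicate 4, and in the longest it was -0.63 and -0.44. Skeletal muscle transcripts divided the AREx libraries another way, with most of them in AREx replicates 2 and 4.

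**Figure D1:**
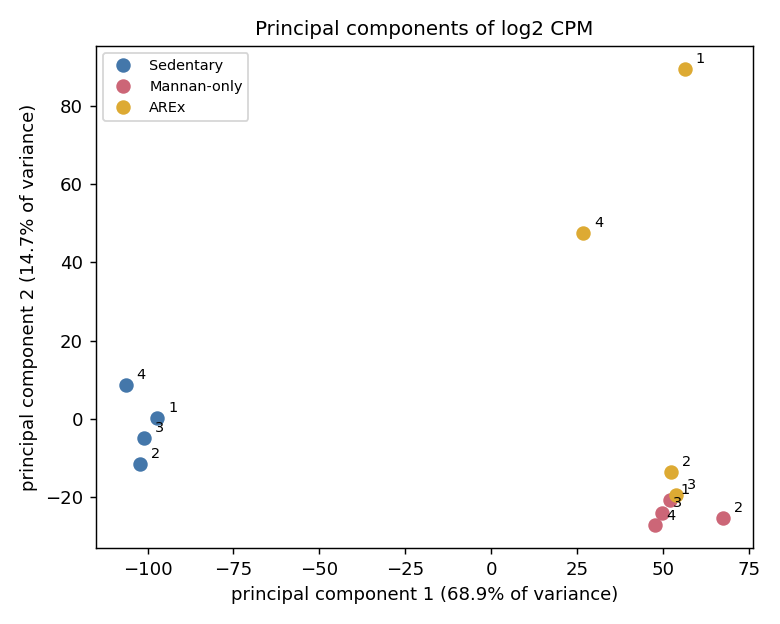
Principal components of log2 CPM, 1 point per library, coloured by group, with the percent of variance on each axis (68.9% and 14.7%). Sedentary libraries lie apart from Mannan-only and AREx along the horizontal axis, and AREx replicates 1 and 4 lie apart along the vertical axis.

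Mannan-only was compared with Sedentary to find which genes differ in the joint after mannan. Of 14278 genes tested, 3749 rose and 3598 fell, and 4068 of these changed by over 2-fold. The collagenase gene Mmp13 (ENSMUSG00000050578, chromosome 9, 7272514 to 7283331, GRCm39) was at 1267 ± 232 CPM in Mannan-only and 0.787 ± 0.464 CPM in Sedentary, and it rose by 10.66 (SE 0.46, adjusted p = 7.09e-08). The cytokine gene Il6 (ENSMUSG00000025746, chromosome 5, 30218112 to 30224979) rose by 7.11 (SE 0.70, adjusted p = 5.71e-06), from 0.404 ± 0.186 to 58.6 ± 27.3 CPM. The osteoclast-forming signal Tnfsf11, also called RANKL (ENSMUSG00000022015, chromosome 14, 78514885 to 78545483), rose by 6.20 (SE 0.28, adjusted p = 8.23e-08), from 0.465 ± 0.130 to 35 ± 3.54 CPM. The fat cell hormone Adipoq (ENSMUSG00000022878, chromosome 16, 22965286 to 22976778) fell by 3.77 (SE 0.40, adjusted p = 8.60e-06), from 1527 ± 363 to 112 ± 38.9 CPM. The groups did not overlap for 63.8% of genes, where chance gives 2.86%.

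**Figure D2:**
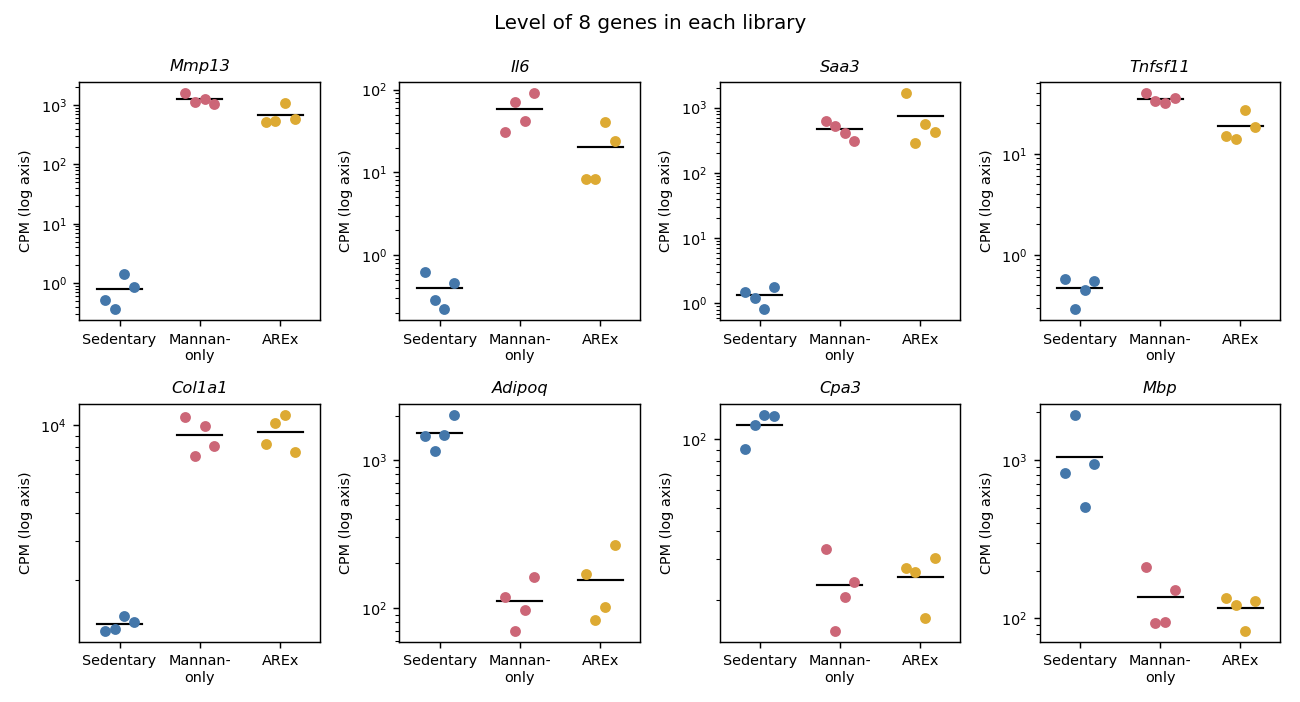
CPM on a log axis for Mmp13, Il6, Saa3, Tnfsf11, Col1a1, Adipoq, Cpa3 and Mbp, with 1 point per library and a line at each group's mean. The 4 Mannan-only libraries lie above the 4 Sedentary libraries for Mmp13, Il6, Saa3, Tnfsf11 and Col1a1 and below them for Adipoq, Cpa3 and Mbp.

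Among the largest rises, Tnn, a tenascin of the matrix (ENSMUSG00000026725, chromosome 1, 159912599 to 159981150), reached 584 ± 98.7 CPM from 0.387 ± 0.157 (log2 change 10.54, SE 0.51, adjusted p = 1.30e-07). Acod1, which makes itaconate in activated macrophages, rose by 9.25 (SE 0.48) and the neutrophil attractant Cxcl5 by 8.76 (SE 0.84). The stefin A family rose, though its near-identical copies make each member's value uncertain. Stfa2l1 rose by 8.68 (SE 1.0), Cstdc5 was 983-fold higher (95% counting interval 336 to 4770) and Stfa2 762-fold higher (136 to 30100), and Cstdc6 was at least 123-fold higher. Kng1 was at least 115-fold and the channel gene Panx3 at least 109-fold higher, each from no read in Sedentary. Among the largest falls, Mrgprg fell by 7.0 (SE 0.70), the macrophage gene Retnla by 5.52 (SE 0.61, 678 ± 158 to 14.7 ± 6.39 CPM) and the oxytocin receptor gene Oxtr by 5.48 (SE 0.34, 60.2 ± 20.8 to 1.34 ± 0.630 CPM). Rnase2a, which has close paralogs, fell by 6.0, Gkn3 by 5.46, Crtac1 by 5.4, Inmt by 4.85, Prr32 by 4.75, Alb by 4.67 and the oxygenase gene Fmo2 by 4.66. Crtac1 overlaps Golga7b, which had few reads.

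Inflammatory signals rose broadly. In this comparison the count adjusted over the list alone was equal where it is not given. Of 19 proinflammatory cytokine genes, 16 rose, 0 fell and 3 did not pass. Il1b rose by 6.58 (SE 0.55, 3.75 ± 3.4 to 366 ± 70.8 CPM), Tnf by 3.31 (SE 0.41) and Il17a was at least 27.1-fold higher (adjusted p = 1.51e-03). As a set this list moved up (adjusted p = 1.69e-07), with an estimated correlation between genes as well (adjusted p = 0.0451). So did the IL-17 response list (adjusted p = 3.20e-09, and 0.0408 with an estimated correlation), in which 21 of 23 members rose and 2 fell. Its members include Saa3 (8.44, SE 0.65), the calprotectin subunit S100a8 (6.31, SE 0.84), Cxcl1 (5.27, SE 0.59), Lcn2, which binds bacterial siderophores (4.15, SE 0.48), and the stromelysin gene Mmp3 (3.81, SE 0.24). Of 29 chemokine genes 23 rose and 2 fell, of 18 TNF and NF-kB response genes 16 rose and 0 fell, and of 17 acute phase and complement genes 13 rose and 2 fell. Of 20 type I interferon response genes 17 rose and 1 fell (18 and 1 adjusted over the list alone). All 12 MHC class II and antigen presentation genes rose, with their regulator Ciita up by 2.40 (SE 0.22). Restraining genes rose as well, 17 of 23 in the anti-inflammatory and checkpoint list with 1 that fell, and Il10 rose by 2.19 (SE 0.54, adjusted p = 4.54e-03). At the preset correlation the chemokine (adjusted p = 1.43e-07), TNF (3.13e-07), interferon (4.49e-06), MHC class II (1.69e-05), anti-inflammatory (1.69e-05) and acute phase (1.09e-03) lists were called. With an estimated correlation their adjusted p was 0.186 for chemokines, MHC class II and acute phase, 0.158 for TNF, 0.277 for interferon and 0.121 for anti-inflammatory genes.

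Markers of blood-borne immune cells were higher. Of 20 neutrophil genes 15 rose and 0 fell (16 adjusted over the list alone), including Csf3r, the receptor for the granulocyte growth factor (6.52, SE 0.52, 8.28 ± 3.16 to 763 ± 187 CPM), and Trem1 (8.24, SE 0.43). Of 27 monocyte and macrophage genes 20 rose, with Spp1 up by 4.04 (SE 0.32), while 3 markers of resident macrophages fell (20 and 4 adjusted over the list alone). These were Cd163 (-2.40 or 37.3 ± 10.6 against 198 ± 59.3 CPM), Lyve1 (-1.71) and Folr2 (-1.16). Of 18 T cell genes 17 rose, among them Cd4 (3.28, SE 0.20), Foxp3 of regulatory T cells (2.16, SE 0.22, overlapping Ccdc22 and Ppp1r3f) and Zap70 (2.25, SE 0.26, 1.10 ± 0.223 to 5.27 ± 0.0986 CPM). All 9 NK and cytotoxic cell genes rose. Adjusted p at the preset correlation was 2.39e-08 for neutrophil, 8.02e-05 for macrophage, 5.15e-08 for T cell and 1.86e-04 for NK genes, and 0.186 for each of them with an estimated correlation. Dendritic cell genes (4 rose, 2 fell, adjusted p = 0.365) and B cell and plasma cell genes (5 rose, 1 fell, adjusted p = 0.200) were not called. Mast cell genes went the other way, with 9 of 10 lower and the list called (adjusted p = 5.07e-04, and 0.189 with an estimated correlation). The mast cell protease gene Cpa3 fell by 2.31 (SE 0.25, 115 ± 16.9 to 23.1 ± 7.78 CPM) and the receptor Mrgprb1 by 2.82 (SE 0.28). The exception, Hdc, makes histamine and is also on the neutrophil list, and it rose by 3.54 (SE 0.28).

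Genes that break down and rebuild joint tissue rose together. In the list of matrix-degrading enzymes and inhibitors 15 of 20 members rose and 2 fell, and the list was called (adjusted p = 3.49e-05, and 0.0408 with an estimated correlation). The members that fell are inhibitors, Timp3 (-2.19, SE 0.19) and Timp4 (-4.55, SE 0.49, 371 ± 76.5 to 15.8 ± 7.46 CPM). All 11 osteoclast genes rose (adjusted p = 6.25e-07, and 0.149 with an estimated correlation). They include the proton pump subunit Atp6v0d2 (4.15, SE 0.18), the fusion gene Ocstamp (5.31, SE 0.40) and the acid phosphatase Acp5 (0.93, SE 0.21, adjusted p = 2.91e-03). Of 11 osteoblast and bone genes 10 rose (adjusted p = 6.64e-05), with the bone sialoprotein Ibsp up by 8.49 (SE 0.89) and the regulator Runx2, which overlaps Supt3, by 2.69 (SE 0.15). Collagen and fibrosis genes (18 of 24 rose and 1 fell, 19 and 1 adjusted over the list alone, adjusted p = 2.89e-07) include Col1a1 (2.85, SE 0.20, 1255 ± 89.9 to 9039 ± 1682 CPM) and Cthrc1 (5.29, SE 0.39). With an estimated correlation the bone and the collagen lists had an adjusted p of 0.186. Of 12 cartilage genes 8 rose (adjusted p = 1.74e-03, and 0.266 with an estimated correlation), including the proteoglycan Acan (6.90, SE 0.76), and of 8 tendon genes 4 rose (5 adjusted over the list alone, adjusted p = 0.0101, and 0.394 with an estimated correlation). Neither synovial fibroblast list was called (lining 2 rose and 1 fell, adjusted p = 0.268, sublining 2 rose and 6 fell, adjusted p = 0.404). The sublining list had a median of 0.02 but a mean of -0.29. The lubricin gene Prg4 (chromosome 1, 150325163 to 150341916) was at 10052 ± 1242 CPM in Mannan-only and 5480 ± 9051 CPM in Sedentary (0.88, SE 0.95, adjusted p = 0.466). Sedentary replicate 2 alone held 19015 CPM, and without it the log2 difference was 3.36 (adjusted p = 8.27e-04).

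Genes of fat cells, of nerve, and of pericytes and smooth muscle were lower. Levels are shares of a library, so a loss of these cells could not be told apart from dilution by others. All 19 adipocyte genes fell (adjusted p = 1.06e-10), with the lipid droplet gene Plin4 down by 3.98 (SE 0.27) and the satiety hormone Lep by 4.43 (SE 0.42, 523 ± 52.6 to 24.2 ± 12.3 CPM). All 16 lipid synthesis genes fell (adjusted p = 5.15e-08), and the triglyceride enzyme gene Dgat2 fell by 3.45 (SE 0.27). Of 18 genes of lipolysis and fatty acid oxidation 14 fell and 1 rose (adjusted p = 1.69e-05), and the fatty acid transporter Cd36 fell by 3.77 (SE 0.34). Thermogenic genes fell in 8 of 9 (adjusted p = 2.56e-03). With an estimated correlation these lists had an adjusted p of 0.186 (adipocyte and lipid synthesis), 0.187 (lipolysis) and 0.190 (thermogenic). All 11 Schwann cell and nerve genes fell (adjusted p = 6.89e-06, and 0.222 with an estimated correlation), among them myelin Mbp (-2.94, SE 0.40) and the glial regulator Sox10 (-3.70, SE 0.50). Pericyte and smooth muscle genes fell in 7 of 12 (adjusted p = 0.0101, and 0.276 with an estimated correlation), while endothelial (3 rose, 4 fell, adjusted p = 0.856) and angiogenesis genes (3 rose, 5 fell, adjusted p = 0.813) were not called. Erythroid genes fell in 6 of 10 (adjusted p = 3.39e-03, and 0.186 with an estimated correlation), with Hbb-bs, which has a near-identical copy, at a log2 change of -2.93 (SE 0.34) and Alas2, which overlaps Apex2, at -2.67 (SE 0.21). The erythroid list also holds Mki67, a gene of dividing cells, which rose by 2.79 (SE 0.28).

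Mitochondrial energy genes were lower and genes of division and cell death higher. Mitochondrially encoded genes fell in 11 of 13 (adjusted p = 5.20e-05, and 0.186 with an estimated correlation), mt-Nd2 among them (-1.43, SE 0.17). Oxidative phosphorylation genes fell in 15 of 18 (16 adjusted over the list alone, adjusted p = 6.99e-05, and 0.359 with an estimated correlation), Sdha among them (-1.07, SE 0.14). Glycolysis genes rose in 8 of 14 and 1 fell (adjusted p = 0.0351, and 0.445 with an estimated correlation), and without Mannan-only replicate 4 the adjusted p was 0.0584. Proliferation genes rose in 19 of 21 (19 higher and 1 lower adjusted over the list alone), pyroptosis and inflammasome genes in 11 of 12 with Nlrp3 up by 4.22 (SE 0.52), apoptosis genes in 10 of 16 with 2 that fell (12 and 2 adjusted over the list alone), and necroptosis genes in 8 of 10. Of the necroptosis genes, Zbp1 rose by 3.4 (SE 0.33), the kinase Ripk3 by 2.68 (SE 0.19) and the executor Mlkl by 0.73 (SE 0.16, adjusted p = 2.30e-03). Adjusted p was 5.15e-08 for proliferation, 1.09e-05 for pyroptosis, 1.74e-03 for apoptosis and 9.04e-04 for necroptosis, and 0.186 for each with an estimated correlation.

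Immediate early genes rose in 9 of 16 (adjusted p = 5.07e-04, and 0.222 with an estimated correlation). Exercise-responsive factors rose in 9 of 18 and 3 fell (adjusted p = 0.0375, and 0.186 with an estimated correlation). The members that fell were Ppargc1a (-2.25), Fndc5 (-2.01) and Vegfa (-1.11). Circadian clock genes fell in 7 of 16 and 1 rose (adjusted p = 0.0375, and 0.359 with an estimated correlation), with the output factors Hlf at a log2 change of -3.14 (SE 0.21) and Tef at -1.60 (SE 0.17). Both calls were lost without AREx replicate 1, which shares the fit (adjusted p = 0.0522 each), and the exercise list also with a stricter filter (0.0982). The clock call was lost too without Sedentary replicate 2 (0.0621) and without Mannan-only replicate 1 (0.0699). Not called were skeletal muscle (0 rose, 1 fell, 0 adjusted over the list alone, median 0.18 while the test pointed down, adjusted p = 0.580), skin and epithelium (1 rose, 3 fell, 1 and 4 adjusted over the list alone, 0.353), heat shock and unfolded protein response (7 rose, 4 fell, median 0.03, mean -0.11 and the test up, 0.580), glucocorticoid targets (4 rose, 4 fell, 0.790), hypoxia and oxidative stress (8 rose, 7 fell, 9 and 7 adjusted over the list alone, 0.438), pain and nociception (6 rose, 2 fell, 0.0735) and cytosolic ribosomal proteins (0 of 20 passed, 0.688).

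Single members moved against lists that were called, and they are named here after their values were seen. The eosinophil attractant Ccl11 fell by 2.41 and Pf4 by 1.02, within the chemokines. The IL-17 receptor chain Il17rc had a log2 change of -0.87. Orm1 (-3.41) and C2 (-0.40) fell among acute phase genes, Ifi27l2a (-2.49) among interferon genes, Klf4 (-1.19) among anti-inflammatory genes, Acta2 (-1.49) among fibrosis genes, and Bcl2 (-1.42) and Bbc3 (-0.61) among apoptosis genes. Ldha (-0.44) fell within glycolysis. Cpt1a (1.04) rose within fat oxidation, Dio2 (1.73) among thermogenic genes and Bhlhe40 (1.39) among clock genes. The calls on Pf4, Bbc3 and Ldha were lost when single libraries were left out, with adjusted p up to 0.0899, 0.104 and 0.137. Bbc3 was lost also with the gene-length trend removed (0.0954), and Ldha with the skeletal muscle score as a covariate (0.0547) and without AREx replicates 2 and 4 (0.0563).

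**Figure D3:**
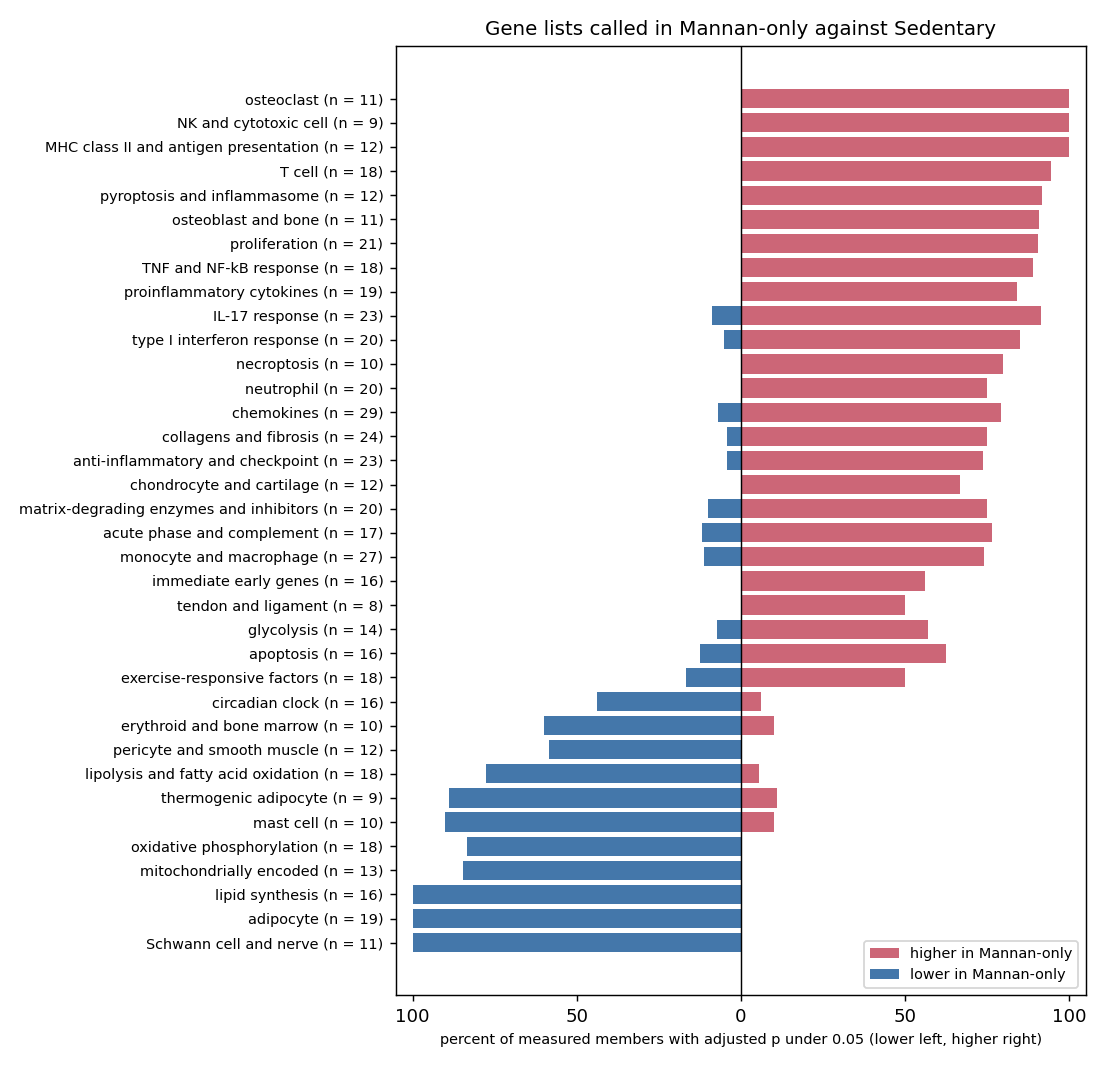
Percent of measured members that rose (right) or fell (left) in Mannan-only against Sedentary for the 36 lists called of 49, each bar 1 list. Osteoclast, MHC class II and NK genes all rose, and adipocyte, lipid synthesis and Schwann cell genes all fell.

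AREx was compared with Mannan-only to ask what low-intensity exercise changes in the arthritic joint. The clock output factor Dbp (ENSMUSG00000059824, chromosome 7, 45354512 to 45359627) was the 1 gene of 14278 that passed. It rose by 2.81 (SE 0.34, adjusted p = 0.0331), from 9.23 ± 4.53 to 64.7 ± 21.8 CPM, and each of the 4 AREx libraries lay above each Mannan-only library. At an unadjusted p under 0.05 there were 2842 genes, DESeq2 called 137 (77 higher and 60 lower), and the groups did not overlap for 6.8% of genes, where chance gives 2.86%. In the authors' deposited table, 438 genes passed, 352 higher and 86 lower, and 26 of them are the skeletal muscle list in full. Without AREx replicate 3 there were 27 calls and without Mannan-only replicate 3 there were 2. The call on Dbp was lost with the skeletal muscle score as a covariate (log2 change 2.48, adjusted p = 0.556) and on leaving out any 1 library other than Mannan-only replicate 3 or AREx replicate 3 (adjusted p = 0.0505 to 0.304), as it was in a fit of the 8 libraries compared (0.266), with the replicate block (0.176) and without AREx replicates 1 and 4 (0.261) or 2 and 4 (0.188), with a log2 change between 2.31 and 3.17 over all settings. Dbp overlaps Sphk2 on the opposite strand.

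The next smallest p-values belonged to genes that did not pass. The D-box factor Tef was at 89.1 ± 7.44 CPM in AREx and 41.3 ± 7.27 CPM in Mannan-only (1.11, SE 0.17, adjusted p = 0.0833), and its repressor counterpart Nfil3 at 34.4 ± 5.61 against 74.2 ± 17.9 CPM (-1.11, SE 0.19, adjusted p = 0.154). The core clock gene Arntl was at 11.7 ± 4.84 against 28.5 ± 2.08 CPM (-1.28, SE 0.24, adjusted p = 0.225) and Per3, which overlaps Camta1, at 36.5 ± 6.14 against 15.7 ± 4.33 CPM (1.22, SE 0.23, adjusted p = 0.233). Pi15 (-0.95, adjusted p = 0.0833), Fam110c (-1.72, 0.0833), the lactate transporter Slc16a1 (-0.71, 0.112), the glycerol kinase Gk (-0.84, 0.190) and Gm14434 (3.71, 0.205) complete the 10. As a list, circadian clock genes were not called (adjusted p = 0.0805), with 1 member past the threshold over all genes, and 8 higher and 4 lower adjusted over the list alone.

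**Figure D4:**
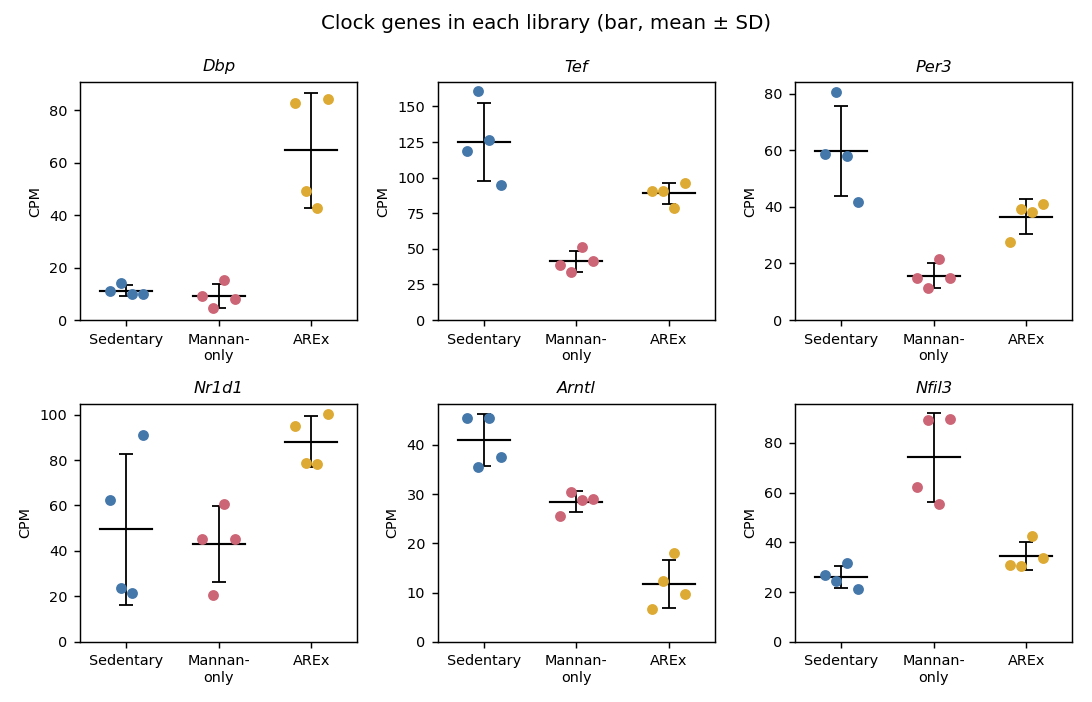
CPM of 6 clock genes (Dbp, Tef, Per3, Nr1d1, Arntl, Nfil3), 1 point per library, with each group's mean ± SD. Dbp, Tef, Per3 and Nr1d1 are higher and Arntl and Nfil3 lower in every AREx library than in every Mannan-only library, and of these genes Dbp alone passed the test over all genes.

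Skeletal muscle genes were the strongest list. All 26 had a positive fold change (median 3.92, adjusted p = 1.49e-16), and all 26 were higher adjusted over the list alone while 0 passed over all genes. With an estimated correlation the adjusted p was 0.659. The fast-fibre gene Tnnt3, which overlaps Prr33, was at 157 ± 169 CPM in AREx and 8.29 ± 9.52 CPM in Mannan-only (4.24, SE 0.99, adjusted p = 0.233), and Tnni2 (3.98), Myl1 (3.62) and Eno3 (2.5) had the same adjusted p. The mean log2 level of the list was 3.18, 6.35, 3.07 and 6.42 in AREx replicates 1 to 4 and 1.34, 0.75, 3.33 and -0.38 in Mannan-only, a difference of 3.49 (exact permutation p = 0.0857, two-sided, n = 4 per group, adjusted 0.467 over the 49 lists). The lists of cytosolic ribosomal proteins (19 of 20 positive, 18 higher adjusted over the list alone, median 0.72, adjusted p = 4.48e-06) and oxidative phosphorylation (17 of 18 positive, 0 adjusted over the list alone, median 0.59, adjusted p = 3.66e-04) were also called up, each with an adjusted p of 0.877 with an estimated correlation. The ribosomal list stood at 10.22 and 9.56 in AREx replicates 1 and 4 and at 8.80 and 8.82 in AREx replicates 2 and 3, beside 8.79 ± 0.06 in Mannan-only. Rps24 was at 1296 ± 1019 against 563 ± 23.1 CPM and Rplp1 at 1445 ± 1007 against 700 ± 33.0 CPM. Without AREx replicates 1 and 4 neither list was called (adjusted p = 0.305 and 0.399). Of the oxidative phosphorylation genes, Ndufb5, which overlaps Mrpl47, had a log2 change of 1.02 and Cox5a of 0.84.

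**Figure D5:**
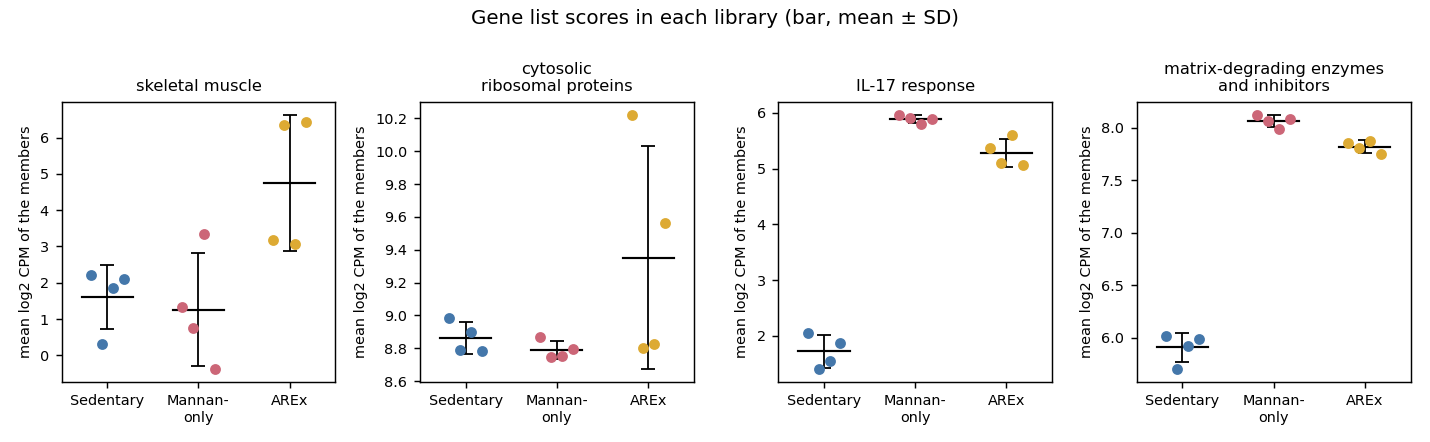
Mean log2 CPM of the members of 4 lists (skeletal muscle, cytosolic ribosomal proteins, IL-17 response, matrix-degrading enzymes and inhibitors), 1 point per library, with each group's mean ± SD. Skeletal muscle is highest in AREx replicates 2 and 4 and ribosomal proteins in AREx replicates 1 and 4, while the IL-17 response is lower in AREx than in Mannan-only by a small part of its distance from Sedentary.

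Inflammatory lists moved down as sets. In the IL-17 response list 21 of 23 members had a negative fold change (median -0.45, adjusted p = 1.07e-03, and 0.659 with an estimated correlation), with 1 higher and 8 lower adjusted over the list alone. The granulocyte growth factor Csf3 was at 0.988 CPM in AREx and 4.09 CPM in Mannan-only (-2.08, SE 0.46), the chemokines Cxcl2 (-1.30) and Ccl20 (-1.29) had the same sign, and the receptor chain Il17rc had the opposite one (0.53, SE 0.14), all with an adjusted p of 0.233. Proinflammatory cytokines (7 of 19 positive, median -0.43, 0 higher and 4 lower adjusted over the list alone, adjusted p = 0.0325, and 0.659 with an estimated correlation) include Il6 at 20.3 ± 15.4 against 58.6 ± 27.3 CPM (-1.52, SE 0.49), Tnfsf11 at 18.6 ± 5.99 against 35 ± 3.54 CPM (-0.91, SE 0.20) and Osm (-0.99, SE 0.31). Angiogenesis genes (3 of 15 positive, median -0.28, 1 lower adjusted over the list alone, adjusted p = 0.0325, and 0.704 with an estimated correlation) include Hif1a at 441 ± 67.6 against 672 ± 11 CPM (-0.61, SE 0.13) and Vegfa (-0.64, SE 0.28). With a stricter filter on low counts the IL-17 call (adjusted p = 0.0638) and the cytokine call (0.0531) were lost, and without AREx replicate 2 the cytokine (0.174) and angiogenesis (0.0683) calls. No list was called by fry, where the smallest adjusted p was 0.0975.

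Among the fixed readouts none passed. Il1b was at 246 ± 56.4 against 366 ± 70.8 CPM (-0.57, SE 0.42, adjusted p = 0.405), Mmp13 at 681 ± 278 against 1267 ± 232 CPM (-0.90, SE 0.30, adjusted p = 0.233), Tnf differed by 0.68 (adjusted p = 0.270), Il17a by -0.57 (0.603), Cxcl1 by -0.45 (0.560) and Il10 by 0.58 (0.422). Log2 differences were below their standard error for Mmp3 (-0.12), Acp5 (0.17), Lcn2 (-0.05), Cxcl5 (-0.21), S100a8 (-0.05), Prg4 (0.05), Lep (0.33), Mlkl (0.14), Ripk3 (0.03) and Zap70 (0.04). Saa3 was at 734 ± 629 against 466 ± 138 CPM (0.65, SE 0.45) and Adipoq at 155 ± 83.1 against 112 ± 38.9 CPM (0.47, SE 0.36). Of the largest arthritis genes, Tnn differed by -0.20, Acod1 by -0.62, Retnla by 1.25, Crtac1 by 1.38 and Fmo2 by -0.51, with adjusted p from 0.233 to 0.704.

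The other lists were not called between AREx and Mannan-only. The closest were type I interferon response (median 0.32, adjusted p = 0.0589), neutrophil (-0.31, 0.0618), chondrocyte and cartilage (-0.93, 0.0805) and erythroid genes (0.33, 0.0859, 4 higher adjusted over the list alone). Adjusted p was 0.139 for endothelial, adipocyte, TNF, exercise-responsive and hypoxia genes, 0.146 for MHC class II, matrix-degrading and necroptosis genes, and 0.178 for anti-inflammatory, collagen and lipid synthesis genes. It was 0.207 for heat shock, 0.230 for osteoclast, 0.232 for immediate early and pain, 0.288 for glucocorticoid, and 0.316 for B cell and lipolysis genes. Median, mean and test differed in sign for the macrophage, sublining fibroblast, acute phase, glycolysis and mitochondrially encoded lists, whose medians lay between -0.05 and 0.10. For the remaining lists the adjusted p lay higher, at 0.454 for dendritic cell, 0.461 for thermogenic, 0.497 for NK, 0.567 for pyroptosis, 0.638 for tendon, 0.654 for skin, 0.681 for lining fibroblast and osteoblast, 0.683 for Schwann cell and apoptosis, 0.692 for mast cell, 0.738 for pericyte and proliferation, 0.758 for sublining fibroblast, 0.816 for glycolysis, 0.884 for macrophage, T cell, chemokine and acute phase, and 0.907 for mitochondrially encoded genes.

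A further question was whether fold changes under exercise oppose those under mannan. Of the 7347 genes changed in Mannan-only against Sedentary, 4728 (64.4%) had the opposite sign in AREx against Mannan-only. Because both comparisons use the Mannan-only libraries, opposite signs arise without any effect. Simulated groups with neither an arthritis nor an exercise effect gave 66.7% (65.9% to 67.7% over 20 simulations). They are no reference for genes that mannan changed. Simulated groups with the arthritis effect but no exercise effect gave 55.9% (54.9% to 57.0%). With the Mannan-only libraries split into 2 and 2, so that none was shared, the share was 56.3% to 67.4%. The covariance of the fold changes was -0.178. It was -0.0463 in simulated unchanged groups and -0.0483 (-0.0601 to -0.0381) in those with the arthritis effect alone. With the Mannan-only libraries split into 2 and 2 it was -0.231 to -0.101, so sharing them does not account for all of it. The simulations drew each gene independently, so their ranges may be too narrow, and an exercise effect stays open. Mmp13, Il6 and Tnfsf11 are among the genes with opposite signs, and Tnf and Saa3 among those without.

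AREx was compared with Sedentary to see what differs from joints given PBS when arthritic mice also ran. Of 14278 genes 3862 rose and 3391 fell. The largest rises included, as in Mannan-only, Tnn (10.34, SE 0.51, adjusted p = 1.87e-07) and Mmp13 (9.76, SE 0.45, adjusted p = 1.32e-07, 681 ± 278 against 0.787 ± 0.464 CPM), with Saa3 (9.09, SE 0.67), Acod1 (8.63, SE 0.48), Cxcl5 (8.55, SE 0.84) and Ibsp (8.17, SE 0.88). The histone gene H2bc24, whose family members are near-identical, was at least 111-fold higher. The largest falls were Mrgprg (-6.32, SE 0.66), the relaxin receptor gene Rxfp1 (-6.11, SE 0.57), Rnase2a (-5.77), Oxtr (-5.62, SE 0.34), Pnpla3 of fat cells (-5.19, SE 0.43) and Fmo2 (-5.17, SE 0.32). Il1b rose by 6.0 (SE 0.53), Il6 by 5.59 (SE 0.69), S100a8 by 6.26 (SE 0.83), Tnfsf11 by 5.29 (SE 0.28), Cxcl1 by 4.82 (SE 0.58), Lcn2 by 4.10 (SE 0.48), Tnf by 3.98 (SE 0.41), Mmp3 by 3.70 (SE 0.24), Il10 by 2.77 (SE 0.52), Ripk3 by 2.71 (SE 0.19), Zap70 by 2.29 (SE 0.26), Acp5 by 1.10 (SE 0.21) and Mlkl by 0.87 (SE 0.16), and Il17a was at least 18.9-fold higher. Lep fell by 4.11 (SE 0.41) and Adipoq by 3.30 (SE 0.39). Prg4 differed by 0.93 (SE 0.95, adjusted p = 0.442), and by 3.41 without Sedentary replicate 2 (adjusted p = 8.05e-04).

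The same tissue themes separated AREx from Sedentary. Counts adjusted over the list alone differed by at most 1 gene per direction here unless they are given. Proinflammatory cytokines rose in 16 of 19 with 1 lower, Il33 (-0.52), and adjusted p was 1.77e-06 (0.0743 with an estimated correlation). The IL-17 response rose in 19 of 23 with 2 lower (adjusted p = 1.55e-08, and 0.0557 with an estimated correlation) and matrix-degrading enzymes in 14 of 20 (1.58e-04, and 0.0557 with an estimated correlation), where Timp3 (-2.26), Timp4 (-3.93) and Plau (-0.81) fell. Other lists called up were neutrophil (17 of 20 rose, adjusted p = 2.23e-08), macrophage (19 of 27, 7.77e-05), T cell (16 of 18, 2.22e-08), NK (9 of 9, 6.93e-05), chemokine (23 of 29, 2.22e-08), TNF (15 of 18, 1.78e-06), acute phase (12 of 17, 1.92e-03), interferon (18 of 20, 2.25e-07), MHC class II (12 of 12, 1.83e-06) and anti-inflammatory genes (17 of 23, 3.71e-05), none of them called with an estimated correlation (0.147 to 0.230). Within them Cd163 (-3.03), Lyve1 (-1.83), Folr2 (-0.74) and Ccl11 (-1.74) fell. Bone and matrix lists called up were osteoclast (10 of 11, 1.78e-06), osteoblast (10 of 11, 9.98e-05), collagen (17 of 24, 1.83e-06), cartilage (9 of 12, 0.0130) and tendon (4 of 8, 0.0194), again not with an estimated correlation (0.176 to 0.486). So were proliferation (20 of 21, 2.22e-08), pyroptosis (12 of 12, 9.08e-06), apoptosis (11 of 16, 2.17e-03), necroptosis (6 of 10, 9.02e-03) and immediate early genes (9 of 16, 1.58e-03), with 0.183 to 0.260 at an estimated correlation. Skeletal muscle was called up here (21 of 26 rose, 22 adjusted over the list alone, median 4.17, adjusted p = 3.38e-04, and 0.488 with an estimated correlation), as were ribosomal proteins (6 rose and 1 fell, 3 higher adjusted over the list alone, 0.0427, and 0.635 with an estimated correlation). The ribosomal call was lost without AREx replicate 1 (0.193), AREx replicate 4 (0.111), Sedentary replicate 2 (0.0740) or Sedentary replicate 4 (0.0715), and without AREx replicates 1 and 4 its direction turned down (0.551). The skeletal muscle call was lost without AREx replicates 2 and 4 (0.0649), which hold most of these transcripts. With the skeletal muscle score as a covariate the cartilage (0.0784) and tendon (0.0996) calls were lost, and tendon also without AREx replicates 1 and 4 (0.0696).

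Lists called down against Sedentary were adipocyte (19 of 19 fell, adjusted p = 2.32e-10), lipid synthesis (16 of 16, 8.50e-09), lipolysis (14 of 18, 2.65e-05), thermogenic (7 of 9, 6.74e-03), Schwann cell (11 of 11, 8.84e-06), mast cell (9 of 10, 4.72e-04), mitochondrially encoded (11 of 13, 4.49e-05), pericyte (8 of 12, 0.0182), erythroid (6 of 10, 0.0108) and oxidative phosphorylation genes (6 of 18, 0.0131). With an estimated correlation their adjusted p ran from 0.183 (lipid synthesis) to 0.561 (oxidative phosphorylation), and none of the 35 lists was called. The oxidative phosphorylation call was lost without AREx replicate 2 (0.0660) or AREx replicate 3 (0.0664). Members that rose within these lists were Hdc (2.31), Mki67 (2.46), Cpt1a (0.91), and the genes Des (1.46) and Fabp3 (2.14, overlapping Zcchc17), which muscle also expresses. Not called were dendritic cell (0.192), B cell (0.0795), lining (0.205) and sublining fibroblast (0.289), endothelial (0.553), skin (0.355), angiogenesis (0.311), glycolysis (0.0552), exercise-responsive (0.136), circadian clock (0.211), heat shock (0.354), glucocorticoid (0.887), hypoxia (0.667) and pain genes (0.143). The sublining list had a median of 0.01 and a mean of -0.30, and the glucocorticoid list a median of -0.07 and a mean of 0.05.

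Composition scores differed from Sedentary in both mannan groups, each with an exact permutation p of 0.0286 (two-sided, the smallest possible, n = 4 per group), adjusted over the 49 lists to 0.0341 in Mannan-only and 0.0359 in AREx, except for skeletal muscle in Mannan-only. The adipocyte score differed by -3.50 in Mannan-only and -3.24 in AREx, cartilage by 2.95 and 2.09, erythroid by -1.85 and -1.42, skin by -0.84 and -0.80, and mitochondrially encoded genes by -1.14 and -1.26. Skeletal muscle differed by -0.35 in Mannan-only (exact permutation p = 0.714) and by 3.14 in AREx. Between AREx and Mannan-only the scores differed by 0.26 for adipocyte, -0.86 for cartilage, 0.43 for erythroid, 0.03 for skin and -0.11 for mitochondrially encoded genes, with exact permutation p from 0.171 to 0.857. From medians over members, erythroid no longer passed in Mannan-only against Sedentary, and cartilage, erythroid and skin no longer passed in AREx against Sedentary.

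The genes changed in Mannan-only and in AREx against Sedentary overlapped in 3044 higher in both and 2808 lower in both, with 0 in opposite directions. Independent lists of these sizes would share 1014.1 and 854.5. With the Sedentary libraries split into 2 and 2, so that no control was shared, 2284 to 2357 genes were higher in both, 2131 to 2313 lower, and 1 to 3 in opposite directions. In the authors' deposited table, 7078 genes passed for Mannan-only against Sedentary, 6379 of them also in the edgeR test made here, and 7089 passed for AREx against Sedentary, 6294 of them also here. In simulated data, the edgeR test recovered 60% of genes changed by 2-fold and 92% of those changed by 4-fold for Mannan-only against Sedentary. For AREx against Mannan-only it recovered 8% at 1.5-fold, 54% at 2-fold and 94% at 4-fold.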

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

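Chosen only after the data were seen were the test on gene length, the test of muscle in AREx replicates 1 and 4 and the tests of the skeletal muscle pattern.

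In groups of 4 libraries, a library was singled out where its distance to the nearest other library took up most of the group's range, which chance gives in about 1 in 20 groups. Of 411 groups from 129 genes, the library totals included, 30 had such a library. The total of Sedentary replicate 1 was 17250000 counts, beside 13460000 to 13830000 in the others. The lubricin gene Prg4 stood at 19020 CPM in Sedentary replicate 2, beside 209 to 1900 CPM in the other Sedentary libraries. Mmp13 was at 1096 CPM in AREx replicate 3, above the other AREx libraries at 513 to 581 CPM, and the chemokine Cxcl2 was highest in the same library at 15.87 CPM (others 7.17 to 8.18), where Gkn3 was low at 0.0722 CPM. In AREx replicate 4 the fat genes Cd36 (302.1 CPM, others 127 to 146) and Plin4 (178.9, others 133 to 137) and the clock gene Bhlhe41 (53.18) were high, and Ciita was low at 44.39 CPM (others 68.0 to 72.2). Ripk3 was high in AREx replicate 1, at 40.38 CPM.

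In Mannan-only replicate 3 the muscle genes Tnnt3 (22.51 CPM, others 2.69 to 4.78) and Myl1 (14.7, others 2.44 to 3.95) were high, and Ripk3 (29.24), Hif1a (655.9) and Fam110c (3.362) were low. In Mannan-only replicate 4 Dgat2 (77.28 CPM), Sdha (185.6), Cpt1a (198) and Orm1 (13.94) were high. Acod1 was high in Mannan-only replicate 2 (176.9 CPM, others 80.5 to 95.9) and Cxcl1 low in Mannan-only replicate 1 (80.87, others 116 to 123). Among Sedentary libraries, Cxcl5 (3.699 CPM) and Zbp1 (12.54) stood out in replicate 1, Cd163 (285.9) in replicate 3, and Dgat2 (940.5) and Bbc3 (9.432) in replicate 4. Genes with almost no read in Sedentary met the criterion through 1 library each, Cstdc5 (0.2339 CPM) and Stfa2 (0.07795) in replicate 4, Csf3 (0.07243) in replicate 2 and Ccl20 (0.0742) in replicate 3.

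AREx replicates 1 and 4 stood apart from AREx replicates 2 and 3 along the axis with 14.7% of the variance. The tables argue against skeletal muscle as the source, since its score in AREx replicate 1 differed from that in AREx replicate 2 by -3.17. A trend on gene length from RNA or library quality stays open. Removing each library's own trend left 0.722 of the squared distance, between the bounds of 0.5 and 0.8 set for and against it before it was run. The library preparation and RNA quality of these samples are not given in the sources used here, so a difference between the mice could not be told apart from it.

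Skeletal muscle genes were higher in AREx, most in replicates 2 and 4. Muscle carried over at dissection is a candidate explanation, since the score varied by 3.71 inside the Mannan-only group, 1.06 times the difference of 3.49 between AREx and Mannan-only. That ratio rests on Mannan-only replicate 3, since without it the ratio was 0.41, under the 0.5 asked for, beside 0.88 to 1.27 without any other library of these groups. A response to exercise in every AREx animal stays open too, as 2 of the 4 AREx libraries lay above the highest Mannan-only library and the exact permutation p was 0.0857. Tnnt3, at 157 CPM in AREx, belongs to fast contractile fibres, and Des of the list is also on the pericyte and smooth muscle list.

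The 8 libraries of each comparison were regrouped in all 35 ways. For genes changed, the real split of Mannan-only and Sedentary gave 7347 and no other split gave any (1 of 35 as large). AREx and Sedentary gave 7253 with 0 at most elsewhere (1 of 35). Every other split puts mannan and PBS libraries on the same side, which widens the spread inside each side. Few calls there are therefore no measure of chance, and 1 of 35 is the smallest share possible. For AREx and Mannan-only, chance cannot be excluded for the 1 gene called, since another split also called 1 (2 of 35). For lists, AREx against Sedentary called 35 (at most 32 elsewhere, 1 of 35) and Mannan-only against Sedentary 36 (at most 37 elsewhere, 4 of 35). Those splits mix the libraries too, so chance is not excluded for the lists of either comparison. In AREx against Mannan-only, 29 of 35 splits called as many lists as the real one, 6, and up to 28, so chance cannot be excluded. Why other splits call more lists was not tested.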

How the results depend on the processing

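The fits without AREx replicates 1 and 4, without AREx replicates 2 and 4 and with the gene-length trend removed were chosen only after the data were seen. For each change below whose setting does not itself explain it, the cause was not tested.

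For Mannan-only against Sedentary, 89 of the 90 genes named passed. Single genes were followed over 19 alternatives, which leave out upper-quartile scaling, limma-voom, the filters and the fits of 8 libraries. Of 1709 values 1687 kept their direction and side of the threshold, 21 no longer passed (Pf4, Bbc3 and Ldha) and 1 newly passed (Prg4 without Sedentary replicate 2). For AREx against Sedentary, 800 of 816 values kept both, 15 no longer passed (Folr2, Des, Il33 and Fabp3) and 1 newly passed, again Prg4. The number of genes changed stayed within 1.5 times of the value reported in both. For AREx against Mannan-only, Dbp no longer passed in 14 of these values and also not in the fit of 8 libraries (adjusted p = 0.266), and 20 genes passed in 38 values, all 20 of them under DESeq2.

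In AREx against Mannan-only the number of genes changed was 1 in the fit reported, 137 with DESeq2, 5 with limma-voom and sample quality weights and 6 with the length trend removed. It was 0 with only the 8 libraries compared (1746 at an unadjusted p under 0.05), 0 with the muscle covariate (1201), 0 without AREx replicates 1 and 4 (663) and 0 without AREx replicates 2 and 4 (3043). Leaving out single libraries gave 0 to 27, the most without AREx replicate 3. With the replicate block it was 0 (3156 at an unadjusted p under 0.05), and besides Dbp (adjusted p = 0.176) the block ended no call of a named gene or a list, while it also called the adipocyte (0.0267) and erythroid (0.0232) lists for AREx against Mannan-only. Replicate numbers did not pair the libraries, as correlations of same-numbered libraries ran from -0.07 to 0.125 and not every library correlated best with its own number.

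With an estimated correlation 3 lists were called for Mannan-only against Sedentary (36 at the preset one), 0 for AREx against Mannan-only and 0 for AREx against Sedentary (35), and fry called 0 for AREx against Mannan-only. Lists called for AREx against Mannan-only were 6 in the fit reported, 4 to 12 on leaving out single libraries (4 without AREx replicate 2, 12 without Mannan-only replicate 2), 12 with the length trend removed and 18 without AREx replicates 1 and 4. In that last fit, at the preset correlation alone, the IL-17 response (adjusted p = 3.02e-05), TNF (9.15e-04) and chemokine lists (1.40e-03) were called. Of the 36 lists called for Mannan-only against Sedentary 33 were called in each of 20 settings, of the 35 for AREx against Sedentary 30, and of the 6 for AREx against Mannan-only 0. Lost calls not given above with their results were, for Mannan-only against Sedentary, the exercise-responsive (0.0893) and clock (0.06045) lists without AREx replicates 1 and 4, and the exercise-responsive list with the length trend removed (0.0558). For AREx against Mannan-only they were skeletal muscle (0.787) and cytokines (0.0708) with the muscle covariate, cytokines (0.175), the IL-17 response (0.0804) and angiogenesis (0.06645) without AREx replicates 2 and 4, and oxidative phosphorylation with the length trend removed (0.502). For AREx against Sedentary they were skeletal muscle with the muscle covariate (0.887) and oxidative phosphorylation without AREx replicates 2 and 4 (0.0564). The share of arthritis genes with an opposite sign, 64.4%, was 53.19% with the muscle covariate, 56.96% without AREx replicates 1 and 4, 57.23% without AREx replicates 2 and 4, and 57.56% (without AREx replicate 4) to 69.91% (without AREx replicate 1) on leaving out single libraries. Composition scores past the threshold for AREx against Sedentary were 6 from means and 3 from medians over members, where cartilage (1.865, adjusted p = 0.0778), erythroid (-0.409, 0.2) and skin (-0.43, 0.274) no longer passed. In Mannan-only against Sedentary the erythroid score from medians, -0.847, no longer passed (adjusted p = 0.07).

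Log2 values that changed sign all belong to genes or scores that did not pass. With the muscle covariate these were Lcn2 (0.492), Cxcl5 (0.067), S100a8 (0.590) and Per1 (0.32) in AREx against Mannan-only. Without AREx replicates 2 and 4 they were Lcn2 (0.492), Cxcl5 (0.339), S100a8 (0.450), Mmp3 (0.091) and Prg4 (-0.079). Without AREx replicates 1 and 4 they were Saa3 (-0.140), Il10 (-0.341), Adipoq (-0.279), Lep (-0.233), Ripk3 (-0.073), Zap70 (-0.262) and Tnn (0.304), and with the length trend removed Acp5 (-0.075), Mlkl (-0.050), Ripk3 (-0.167) and Zap70 (-0.093). On leaving out single libraries, the lowest and highest values were -0.284 and 0.067 for Mmp3, -0.134 and 0.924 for Saa3, -0.607 and 0.258 for Lcn2, -0.882 and 0.034 for Cxcl5, -0.838 and 0.256 for S100a8, -0.058 and 0.226 for Prg4, -0.038 and 0.660 for Lep, -0.071 and 0.073 for Ripk3, -0.186 and 0.203 for Zap70, and -0.423 and 0.043 for Tnn. The muscle score in Mannan-only against Sedentary ran from -1.044 to 0.195 and the skin score in AREx against Mannan-only from -0.099 to 0.115.

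For the scores, leaving out a library gives a smallest exact permutation p of 0.0571 (35 assignments, 4 against 3), so no test could pass. Alternatives meant for a table without counts were not run, since counts were given. At this depth 54% of simulated 2-fold changes between AREx and Mannan-only were recovered, and 8% of 1.5-fold changes.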

Other observations

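Chosen only after the data were seen were the test of a different clock time at tissue collection, the test of AREx replicates 1 and 4 as a source of the Dbp difference, and the fits of the IL-17 response without pairs of AREx libraries.

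Clock genes beyond those described above also differed between AREx and Mannan-only, named here after their values were seen. Dbp stood at 64.7 ± 21.8 CPM in AREx, 9.23 ± 4.53 in Mannan-only and 11.2 ± 2.01 in Sedentary (n = 4 each). Nr1d1, which represses Arntl, was at 88.1 ± 11.4 CPM in AREx and 42.9 ± 16.7 in Mannan-only, Nr1d2 at 92.1 ± 21.4 and 47.8 ± 15.7, Ciart at 3.21 and 1.42, and Bhlhe41 at 34.6 and 19.5. Of the activators, Npas2 was at 8.61 CPM in AREx and 20.6 in Mannan-only, and Clock at 62.4 and 78.8. Values did not overlap between AREx and Mannan-only for Dbp, Tef, Per3, Nr1d1, Ciart, Bhlhe41, Arntl, Npas2, Clock and Nfil3, each with an exact permutation p of 0.0286, two-sided, the smallest possible with 4 against 4, and Dbp alone passed adjustment over all genes.

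Clock genes also differed between Mannan-only and Sedentary, in another pattern. Collection times are not given for any group, so mannan and a shift of collection could not be told apart as its source. Tef went from 125 ± 27.2 CPM in Sedentary to 41.3 ± 7.27 in Mannan-only and 89.1 ± 7.44 in AREx, and Per3 from 59.7 ± 15.9 to 15.7 ± 4.33 and 36.5 ± 6.14. The repressor Nfil3 was at 26.1 ± 4.37, 74.2 ± 17.9 and 34.4 ± 5.61 CPM in the same order. Hlf was low in both mannan groups (51.2, 5.79 and 9.03 CPM).

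A candidate explanation is that AREx tissue was collected at another clock time than Mannan-only tissue. Of 14 genes with a known phase, picked after their values were seen, 13 had the sign that a shift toward the peak of Dbp predicts, with Per1 the exception (-0.41, SE 0.40). That choice keeps the count from deciding, and the clock list members Cry1 (-0.468), Cry2 (0.243) and Bhlhe40 (-0.34) were not in it. Collection times are not given in the sources used here, so a shift of collection, a clock shifted by training and a direct response to running could not be told apart. The tables argue against AREx replicates 1 and 4 as the source, since without them the log2 change of Dbp was 2.31 (SE 0.33). They also argue against muscle, since with its score as a covariate the change was 2.48 (SE 0.44), although its adjusted p was then 0.556 with a wider error, within a range of 5.76e-13 to 0.556 over all settings.

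The lower IL-17 response in AREx might be carried by part of the libraries. Its score was 5.37, 5.11, 5.60 and 5.06 in AREx replicates 1 to 4 and 5.80 to 5.97 in Mannan-only, so the groups did not overlap, with an adjusted p of 0.35 over the 49 lists. Without AREx replicates 1 and 4 the list had an adjusted p of 3.02e-05 at the preset correlation. It was not called with an estimated correlation (0.659), which was run on all libraries alone. Without AREx replicates 2 and 4 its adjusted p was 0.0804. A fresh set of animals with recorded collection times would be needed to tell whether exercise lowers it.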
